A study of Mus musculus with 9 samples.

How the data were processed

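The samples were J1 mouse embryonic stem cells, and 9 two-channel arrays were used, 3 per group: M14_vs_SCR, DZA_vs_SCR and M14_vs_M14, named by the Cy5 and then the Cy3 RNA. Groups and replicate numbers were taken from the labels. The design text speaks of biological replicates; p-values measure the spread between these arrays only. No array had swapped dyes, and the design text names the M14_vs_M14 arrays as the control for the dye difference. Per the labels' design text each array holds 947952 probes of 25 nt that overlap their neighbours by 19 nt, and per the extract protocol polyadenylated RNA was purified before labelling.

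Per the file headers, spot intensity was read by Agilent Feature Extraction 10.7.3.1, which gives mean and background intensity in each channel, background-subtracted and dye-normalized processed intensity, a log10 ratio of the processed signals, and flags as other values. The deposited series table holds log2 values. It was matched by row number; these values are missing exactly where a spot was not above its local background, and they correlate with log2(Cy5/Cy3) across spots (r between 0.938 and 0.972 over the 9 arrays), so their direction is Cy5 over Cy3. The submitters' processing notes name limma, and its settings are not given in the sources used here. The grid named mm9 in the file headers, but the coordinates match GRCm38: 89.7% of the regions lay inside a gene of the GRCm38 annotation, against at most 68.8% when shifted by 5 kb or more, and the share was highest with no shift on 20 of 21 chromosomes. Coordinates are therefore given on GRCm38.

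Mean signals were corrected with limma's normexp method against the median local background (offset 50) and normalized within each array by loess (limma 3.58.1, R 4.3.3, with the data.table package at version 1.17.8). Of 954073 spots per array, 6121 were controls. The other probes fall in 2 classes in the files' region names, 936014 in 8423 regions with the prefix m6a and 11938 in 50 regions with the prefix neg. Main results use the first class. A probe was kept when it was well above background in both channels on at least 3 of the 9 arrays and unflagged on all 9, which kept 622430 (66.5%); 2895 probes were left out for a flagged spot. No spot was saturated. Probes were read as antisense to the RNA: as spotted, 3.54% of them held AGTCC, the reverse complement of GGACT, and 2.22% held GGACT. Their order within regions was checked on 212 pairs of regions that overlap on opposite strands.

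Regions were named by the single protein-coding gene they overlap in the GRCm38 annotation, or else the single long noncoding RNA, whatever the strand, which the annotation used does not give: 7452 of 8423 regions (88.5%) lay in 5253 genes, 378 of them also over a long noncoding RNA; 406 overlapped several genes and 565 none, and these stayed separate units. A gene's value is the median over its kept probes, at least 5, with a median of 70. This left 6038 units, 5177 named genes and 861 unnamed regions; 286 units hold kept probes on both strands. A probe's local value is its log2 ratio minus the median of its tiled region on that array (regions with at least 5 kept probes, 621747 probes).

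Each level was fitted over all 9 arrays with limma's lmFit and eBayes and Benjamini-Hochberg adjustment with a threshold of 0.05. M14 and DZA were each tested against M14_vs_M14, and DZA against M14. The GGACT test compares, per array, probes with the adenosine of GGACT at positions 9 to 17 of the 25-mer with probes without DRACH, matched on G plus C, by an exact permutation test. Gene lists (16, of which 13 had at least 5 measured genes) were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The rule for named genes, the tests, the lists and most alternatives were fixed before the data were examined. The named genes are Mettl14, which is not tiled, the 10 largest rises and 10 largest falls of each gene comparison among those past the threshold with all 3 arrays apart, the 5 largest each way between DZA and M14, and the 4 members of each list with the smallest p in each comparison; for local probes the 5 largest each way, 1 per region. Other list members are named to complete a list, after their values were seen.

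The replicate numbers may pair the M14_vs_SCR and M14_vs_M14 arrays, which are called the paired arrays below. Deviations from the group means correlated across genes at 0.341, 0.280 and 0.217 for numbers 1, 2 and 3. Only 2 of the 3 M14_vs_SCR arrays correlated best with their own number, so the pairing is uncertain. DZA_vs_SCR arrays did not pair with the M14_vs_M14 arrays (-0.168, -0.198 and 0.037). A fit with the number as a block is among the alternatives. The others change the background correction, the normalization, the source of the values, the filter on dim probes, the dye control, the summary per gene or region, the variance prior and the motif, and leave out each array in turn. Probe words of 14 nt shared with another gene or region were listed after the data were examined; 46.1% of kept probes have one.

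The fits were tested on simulated arrays with independent noise, its variance drawn from the prior of the fit over all 9 arrays, and 200 items changed. They hold none of the likeness between real arrays. Among 6038 genes the simulated M14 vs SCR test recovered 77.9% of changes of 0.2 (log2), 95.5% of 0.4 and 100% of 0.8, with 9 false calls. Among 621747 local probes it recovered 1.47% of changes of 0.5, 42.4% of 1 and 89.4% of 2. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.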

Results

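RNA from J1 mouse embryonic stem cells was hybridised to 9 two-channel Agilent tiling arrays that carried short probes against stretches of transcripts reported to bear N6-methyladenosine (m6A), a methyl mark on adenosine in messenger RNA. In 3 arrays the Cy5 channel held RNA from cells that the labels call M14, and the Cy3 channel held RNA from scrambled-control cells (SCR). The sample characteristics and the design text describe M14 as cells lacking Mettl14, a subunit of the m6A methyltransferase, while the sample titles read MettL4, the name of another gene. In 3 arrays Cy5 held RNA from cells labelled DZA and Cy3 again held SCR RNA. In the last 3 arrays both channels held M14 RNA, so that the Cy5 to Cy3 ratio there shows the difference between the dyes. The labels call M14 both a knockout and a transfection with siRNA, and call DZA both a mutant and an siRNA target; the names M14 and DZA are used here without choosing. No tiled region lay in Mettl14, so its own level was not measured.

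The arrays read 936014 probes in 8423 tiled regions, and 7452 of these regions lay in a single named gene. Median spot brightness was between 62.1 and 102 units in Cy3 and between 24 and 84.4 in Cy5, over background medians of 22 to 24.5 and 18 to 21. The share of spots well above background in both channels ran from 43.8% in M14_vs_M14 replicate 2 to 74.1% in DZA_vs_SCR replicate 2. Cy5 was brighter on replicate 1 of M14_vs_SCR (median 67.6) than on its replicates 2 and 3 (27.1 and 28.8), and on replicate 1 of M14_vs_M14 (50) than on its replicates 2 and 3 (24 and 24.6). On the DZA_vs_SCR arrays it was 32.8, 84.4 and 39.3. Each array had its own slide, and no technical batch was recorded that held more than 1 group. The number of arrays, 3 per group, limits the precision of every value below. Each change is a log2 ratio of the named group minus that of the M14_vs_M14 arrays, with the SE of the limma fit and n = 3 arrays per group; adjusted p-values are limma's with Benjamini-Hochberg adjustment over 6038 genes and unnamed regions, and coordinates are on GRCm38.

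The M14 arrays ask which transcripts change in M14 cells, read here as cells that lost Mettl14. Ccn1 (chromosome 3, 145647458 to 145648054) rose most, by 1.51 ± 0.18 on the log2 scale (limma adjusted p 0.000854). Its 3 arrays averaged 1.45 ± 0.41 (SD) against -0.06 ± 0.02 on the dye control arrays. Igfbp3 rose by 1.38 ± 0.13, Fgfbp1 by 1.27 ± 0.09, Ltb by 1.17 ± 0.16, Arl4c by 1.10 ± 0.12, Gja1 by 1.09 ± 0.09 and Cldn6 by 1.05 ± 0.11, with limma adjusted p-values from 8.75e-05 (Fgfbp1) to 0.00175 (Ltb). Adgrl2 (0.93 ± 0.16) and Sfn (0.91 ± 0.10) completed the named genes that rose, and 1 unnamed region on chromosome 18 (9595678 to 9595858) rose by 1.21 ± 0.14.

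Among the largest falls in M14 cells, S100a7l2 changed by -1.27 ± 0.10, Fgf12 by -1.14 ± 0.09 and Gng12 by -0.92 ± 0.08 (limma adjusted p 8.75e-05, 8.75e-05 and 0.00015). These 3 genes and the 6 unnamed regions with the largest falls are read mostly by probes that share a word of 14 nt with other tiled regions: 85.7% of the kept probes of S100a7l2, 100% of those of Fgf12 and 71.4% of those of Gng12. The 6 regions lie on chromosome 2 (22002292 to 22002599), chromosome 4 (56434947 to 56435376 and 75354636 to 75354898) and chromosome 3 (6297908 to 6298113, 6300402 to 6300977 and 6305813 to 6306176), with changes from -1.17 to -0.95. Mymx, with 41.3% of its 104 kept probes sharing a word, fell by 1.01 ± 0.11 on the log2 scale (limma adjusted p 0.000641). In all, 1731 of 6038 genes and regions passed an adjusted p of 0.05, 1008 higher and 723 lower. The count was 850, 755 and 744 without M14_vs_M14 replicate 1, 2 or 3, and 0 with median centring in place of loess (limma, 721 at an unadjusted p below 0.05). All 1731 had their 3 arrays apart from the 3 dye control arrays, which was true of 58.0% of all 6038 where chance gives 10%. Single probes past the threshold numbered 6097 of 622430 (3799 higher, 2298 lower), but between 1658 and 5045 with 1 array left out and 562 with median centring. The dye control arrays themselves called 2 genes against 0 (645 at an unadjusted p below 0.05). At the level of single probes they called 3903 against 0 (814 higher, 3089 lower).

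**Figure D1:**
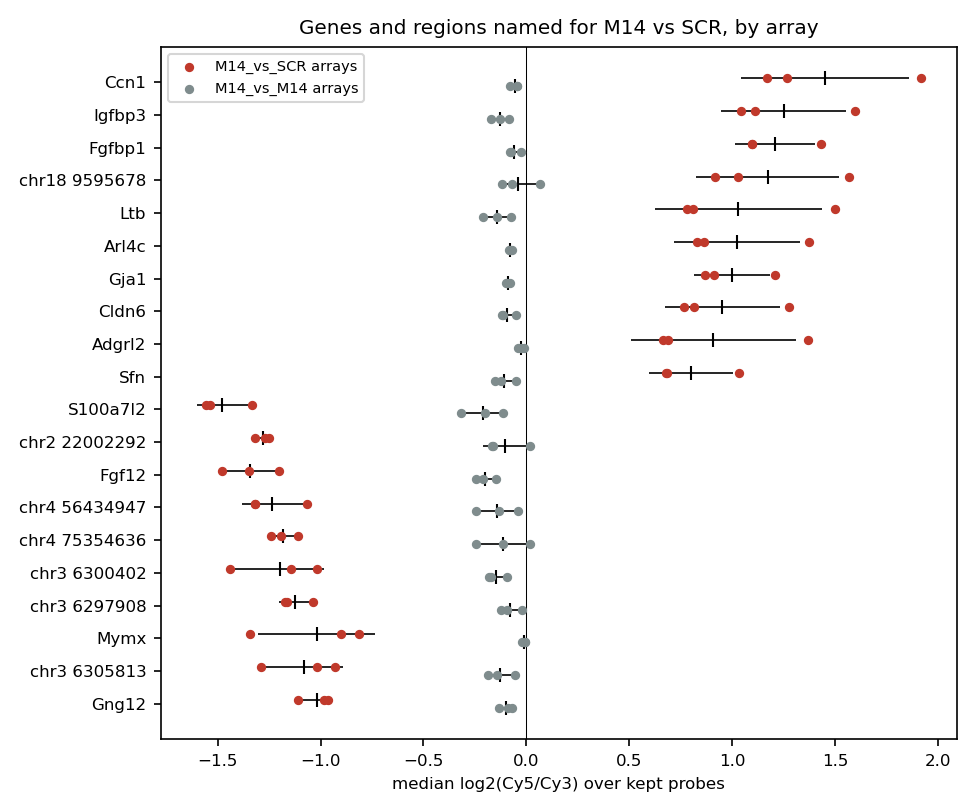
Median log2(Cy5/Cy3) over the kept probes (horizontal axis) of the 20 genes and regions with the largest changes in M14 cells, for each of the 3 M14_vs_SCR arrays (red) and the 3 M14_vs_M14 arrays (grey), with the mean (tick) and SD (line). Ccn1 reaches 1.92 on M14_vs_SCR replicate 1 and lies near -0.06 in the dye controls.

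Genes of the naive pluripotent state fell in M14 cells. Of the 14 measured, 10 fell and none rose past the threshold, both over all genes and adjusted over the list alone, and the median change was -0.25. Tet2 changed by -0.61 ± 0.11, Klf4 by -0.46 ± 0.07, Tbx3 by -0.43 ± 0.11, Gbx2 by -0.39 ± 0.07, Tet1 by -0.36 ± 0.04 and Zfp296 by -0.32 ± 0.05, with limma adjusted p-values from 0.000759 (Tet1) to 0.0174 (Tbx3). Myc (-0.25 ± 0.03), Fgf4 (-0.26 ± 0.07), Nr5a2 (-0.17 ± 0.03) and Klf2 (-0.16 ± 0.03) also fell. Sox2 (-0.05 ± 0.04), Sall4 (-0.05 ± 0.06), Trim71 (-0.03 ± 0.04) and Gdf3 (-0.03 ± 0.04) did not pass. Set against all other genes with limma's camera at a preset correlation of 0.01, the list had an adjusted p of 4.29e-06 over 13 lists. With the correlation estimated from the arrays, the adjusted p was 0.0732 and no list passed. Kept probes of Gbx2, Klf2, Sox2, Tet1 and Tet2 lie on both strands, and the change was -0.23 on the plus and -0.65 on the minus strand of Gbx2 and -0.07 and -0.69 on those of Tet2. Among fibroblast feeder markers Ccn1 (1.51 ± 0.18) and Twist1 (0.40 ± 0.09) rose in M14 cells and Col5a1 (0.16 ± 0.08) did not pass, and a larger share of feeder cells would lower naive genes too.

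Of 10 primed and formative genes measured, 5 rose and 1 fell in M14 cells. Otx2 rose by 0.66 ± 0.10, Pou3f1 by 0.45 ± 0.07, Sall2 by 0.25 ± 0.07, Zic2 by 0.19 ± 0.05 and Sox3 by 0.15 ± 0.04, while Lefty2 fell by 0.17 ± 0.05 and Cdh2, Nodal and Foxd3 did not pass. The list's camera adjusted p (limma, Benjamini-Hochberg) was 0.0381 at the preset correlation and 0.571 with an estimated one. Adjusted over the list alone, 6 rose and 1 fell. Of 23 immediate early genes, 14 rose and 2 fell, among them Klf6 (0.65 ± 0.08), Jun (0.47 ± 0.08), Dusp4 (0.42 ± 0.05), Btg1 (0.32 ± 0.04) and Spry2 (-0.18 ± 0.03, reversed under median centring without loess). Over that list alone 14 rose and 5 fell, and its camera adjusted p (limma) was 0.0237 at the preset correlation and 0.611 at the estimated one. With a block over the paired M14_vs_SCR and M14_vs_M14 arrays only, neither of these 2 lists passed (camera adjusted p 0.0557 for both). The primed list also did not pass without the dye control (0.0928) or with a channel balance covariate (0.0803).

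Single members of other lists moved in M14 cells although none of the other lists tested passed camera. With limma's fry, which does not compare a list with other genes, the interferon response list passed in M14 cells (adjusted p 0.00259). The integrated stress response (0.00316) and cell cycle (0.0244) lists passed fry too. The median change of each of these lists was downward and smaller than 0.10 on the log2 scale. Most members of each were not measured, and most of those measured did not pass the threshold. Bmp4 fell by 0.73 ± 0.11, Suz12 by 0.49 ± 0.06, Trib3 by 0.43 ± 0.09, Suv39h1 by 0.35 ± 0.09, Lifr by 0.33 ± 0.05, Sesn2 by 0.30 ± 0.05, Trim25 by 0.29 ± 0.02 and Smad7 by 0.29 ± 0.03. Nes rose by 0.55 ± 0.08, Gusb (the only measured gene of the housekeeping list, which was not tested) by 0.44 ± 0.04, Fzd7 by 0.38 ± 0.05, Foxa2 by 0.33 ± 0.07 and Ddit4 by 0.23 ± 0.03. Among the m6A writers and erasers Wtap rose by 0.15 ± 0.03, Virma by 0.16 ± 0.05, Rbm15 by 0.10 ± 0.03 and Rbm15b by 0.10 ± 0.03, and Fto fell by 0.14 ± 0.03 (limma adjusted p from 0.00838 to 0.0428). None of the 7 m6A readers measured passed, with Ythdf2 at 0.14 ± 0.05. The camera adjusted p-values (limma) of the other 10 lists ran from 0.31 to 0.919.

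**Figure D2:**
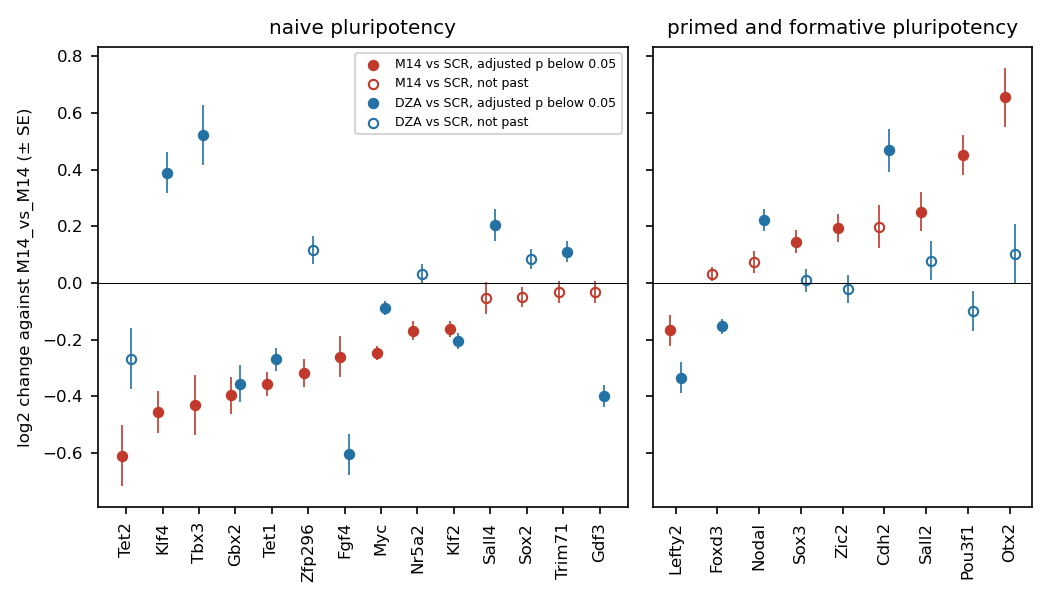
Log2 change against the M14_vs_M14 arrays (vertical axis, with its SE as a bar) of the 14 naive pluripotency genes measured and 9 of the 10 primed or formative ones, in M14 (red) and DZA cells (blue), from 3 arrays per group. Filled points passed an adjusted p of 0.05, and all 14 naive genes lie below 0 in M14 cells.

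The DZA arrays ask the same of cells labelled DZA. Ccn1 again rose most, by 1.33 ± 0.18 (limma adjusted p 0.00082), its 3 arrays averaging 1.27 ± 0.23 (SD). Eps8 rose by 1.07 ± 0.07, the noncoding RNA A730017L22Rik by 0.96 ± 0.05, Zfp580 by 0.95 ± 0.08, Mdm2 by 0.87 ± 0.05, Dph5 by 0.85 ± 0.08 and Ahnak by 0.83 ± 0.11. Rbmxl2 (chromosome 7, 107209385 to 107210734) changed by -1.5 ± 0.09 (limma adjusted p 2.24e-05), followed by Rian (-0.85 ± 0.07), H1f0 (-0.83 ± 0.06), Imp3 (-0.78 ± 0.05), 2010320M18Rik (-0.78 ± 0.07), Sephs2 (-0.77 ± 0.04), Mymx (-0.73 ± 0.11) and Myrf (-0.69 ± 0.09). Gm35197 rose by 1.17 ± 0.09, read by 8 kept probes that all share a word with other regions.

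A region over Stk16 and Tuba4a on chromosome 1 (75215572 to 75217047) fell by 0.81 ± 0.06 in DZA cells and an unnamed one on chromosome 6 (67205715 to 67205952) fell by 0.79 ± 0.07. A region over Gm21992 and Rbm14 on chromosome 19 (4803093 to 4804192) rose by 0.86 ± 0.06. An unnamed region on chromosome 9 (50085991 to 50086217) rose by 0.94 ± 0.09, from 10 probes that all share a word with other regions. In all, 2564 genes and regions passed, 1404 higher and 1160 lower, and 2546 of them had their 3 arrays apart from the 3 dye control arrays. Agilent's signals gave 1341 higher and 495 lower, and median centring in place of loess gave 0 (limma, 731 at an unadjusted p below 0.05). Single probes past the threshold numbered 17883 (10770 higher, 7113 lower), but between 1486 and 34087 with 1 array left out and 0 with median centring (limma, 50513 unadjusted).

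**Figure D3:**
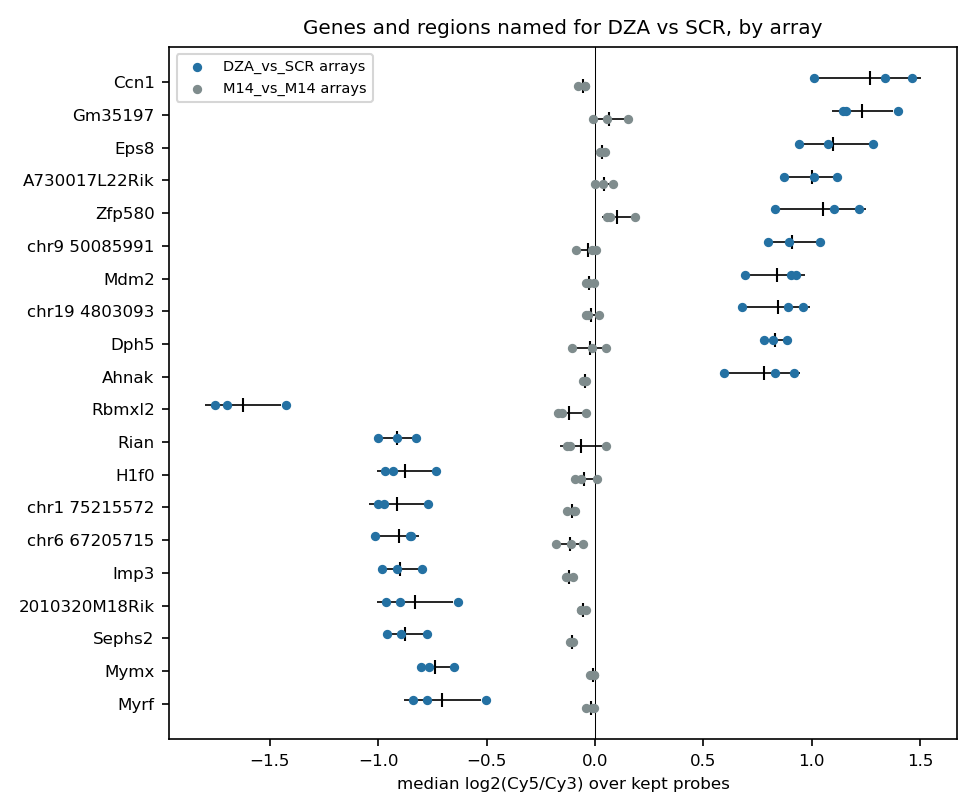
Median log2(Cy5/Cy3) over the kept probes (horizontal axis) of the 20 genes and regions with the largest changes in DZA cells, for each of the 3 DZA_vs_SCR arrays (blue) and the 3 M14_vs_M14 arrays (grey), with the mean (tick) and SD (line). Rbmxl2 shows the largest fall, 1.5 below the dye controls.

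The naive pluripotency genes moved in both directions in DZA cells. Their list did not pass camera, but it passed limma's fry (adjusted p 0.0172), which does not compare a list with other genes. Tbx3 (0.52 ± 0.11), Klf4 (0.39 ± 0.07), Sall4 (0.21 ± 0.06) and Trim71 (0.11 ± 0.04) rose, while Fgf4 (-0.60 ± 0.07), Gdf3 (-0.40 ± 0.04), Gbx2 (-0.35 ± 0.07), Tet1 (-0.27 ± 0.04), Klf2 (-0.20 ± 0.03) and Myc (-0.09 ± 0.03) fell, with Gdf3 and Klf2 reversed under median centring without loess. Among p53 targets Mdm2 and Plk2 (0.63 ± 0.05) rose and Bbc3 (-0.41 ± 0.04) fell. In the integrated stress response Trib3 (-0.58 ± 0.09) and Chac1 (-0.57 ± 0.07) fell and Atf3 (0.52 ± 0.09) rose. Of 15 Polycomb and histone methyltransferase genes 9 rose, led by Kmt2d and Kmt2a (both 0.18 ± 0.03), and Suv39h1 fell by 0.39 ± 0.09. The m6A readers Ythdf2 (0.31 ± 0.05), Ythdf1 (0.24 ± 0.04), Ythdc1 (0.13 ± 0.04) and Ythdf3 (0.13 ± 0.03) and the factors Alkbh5 (0.27 ± 0.05), Rbm15 (0.18 ± 0.03), Virma (0.17 ± 0.05) and Zc3h13 (0.14 ± 0.03) rose. Klf6 (0.66 ± 0.08), Nes (0.48 ± 0.08), Cdh2 (0.47 ± 0.08) and Msx2 (0.42 ± 0.04) rose too, and Socs3 (-0.32 ± 0.03), Ddx58 (-0.31 ± 0.05) and Neat1 (-0.20 ± 0.04) fell, of which Socs3 and Neat1 reversed under median centring without loess. No list passed limma's camera at the preset correlation, where the smallest adjusted p of 13 lists was 0.224, or with an estimated correlation. At an unadjusted p below 0.05 camera gave 2 lists, lineage differentiation (0.0276) and Polycomb (0.0349).

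Tested directly against each other, DZA and M14 cells differed at 2730 genes and regions, 1377 higher in DZA and 1353 lower. Agilent's signals gave 1343 higher and 736 lower, and median centring gave 0 (limma, 271 unadjusted). Rian differed by -1.48, having risen by 0.63 ± 0.07 in M14 cells and fallen by 0.85 ± 0.07 in DZA cells (limma adjusted p of the difference 5.04e-06). Regions were named without regard to strand, and the 33 kept probes of Rian lie on the plus strand. Rbmxl2 (-1.36), Ltb (-1.10), Klf4 (0.84), Tbx3 (0.96), Mdm2 (1.03), Suz12 (0.64), Bmp4 (0.63), Otx2 (-0.55) and Pou3f1 (-0.55) also differed, with limma adjusted p-values between 9.39e-06 (Mdm2) and 0.00257 (Otx2). The fall of Mdm2 in M14 cells (-0.16 ± 0.05) reversed to 0.0024 under median centring without loess. Ccn1 (-0.18) and Sfn (-0.15) did not differ past the threshold between DZA and M14 cells. The largest differences were those of S100a7l2 (1.72), Gm35197 (1.72), the chromosome 9 region (1.59), Fgf12 (1.54) and the chromosome 3 region from 6297908 (1.49), all read mostly by shared probes. An unnamed chromosome 4 region (41878794 to 41878856) differed by -1.23 and the chromosome 18 region from 9595678 by -1.44.

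**Figure D4:**
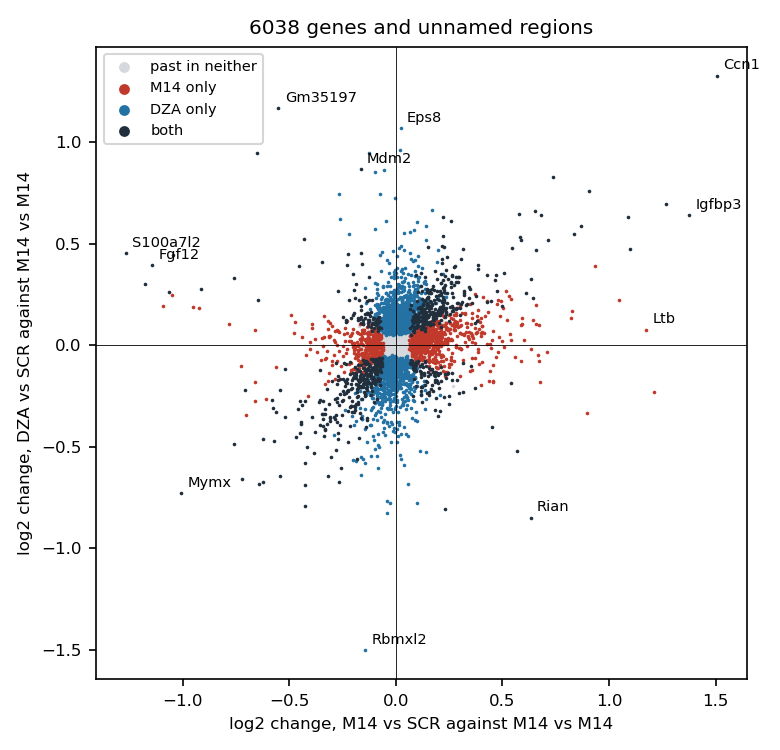
Log2 change of 6038 genes and unnamed regions in M14 cells (horizontal axis) and DZA cells (vertical axis), each against the same 3 M14_vs_M14 arrays; colours mark which comparison passed an adjusted p of 0.05. Ccn1 lies high in both, and Rian, S100a7l2 and Gm35197 lie in opposite quadrants.

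Called genes were shared by both comparisons in the same direction for 304 that rose and 278 that fell, where independent lists of these sizes would share 234 and 139. Opposite calls numbered 97 and 84, against 194 and 168. Across genes, which are not independent replicates, the changes correlated at r = 0.311. Unchanged groups simulated against the same dye control arrays gave 0.501, since both comparisons subtract those 3 arrays. The covariance was 0.00706 against a simulated 0.000772, a difference of 0.00629. With separate control arrays, 1 for one comparison and the other 2 for the other, a test chosen after the data were seen, r was between 0.278 and 0.307 over the 6 ways, so noise in shared control arrays accounts for little of the overlap. Both comparisons also share SCR RNA in Cy3, and a property of the SCR cells would move both alike, which these arrays cannot separate.

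The array was designed to find where in a transcript hybridisation rises when methylation is lost, so each probe was also measured relative to the median of its tiled region. At that level 137 of 621747 probes passed in M14 cells (74 higher, 63 lower) and 81 in DZA cells (56 higher, 25 lower). The dye control arrays alone, tested against 0, called 2576 local probes (733 higher, 1843 lower), more than either comparison. With the replicate number as a block 0 probes passed in M14 cells (limma, 24054 at an unadjusted p below 0.05), and 4060 with that block over the paired arrays only. The directions depended on the processing. In M14 cells 48 were higher and 72 lower without background correction, 76 and 112 with Agilent's signals, 9 and 24 with spots well above background on all 9 arrays, 78 and 130 with the gene median taken out and 1828 and 2232 with the block over the paired arrays. In DZA cells the split was 27 higher and 26 lower without background correction, 2 and 14 with Agilent's signals, 1 and 14 with the series matrix and 1 and 5 with the block. In M14 cells the largest local rise was in Arl4c (probe GCGAGAACCCGCGAACAAAGACAAC on the RNA strand, 1.68 ± 0.10, limma adjusted p 0.00733), followed by probes in Rccd1 (1.40 ± 0.14), Ccn1 (1.26 ± 0.08) and Pdpn (1.21 ± 0.14) and in an unnamed chromosome 6 region (1.30 ± 0.13). The largest local falls lay in Vrtn (-1.76 ± 0.19), Spata13 (-1.46 ± 0.15), Mrps2 (-1.44 ± 0.09), Arl4c (-1.44 ± 0.13) and Fgfbp1 (-1.41 ± 0.16). In DZA cells the largest local rises lay in Adgra3 (1.86 ± 0.12), Plod1 (1.52 ± 0.11), Snx29 (1.5 ± 0.11), Pcdh1 (1.48 ± 0.13) and Rbmxl2 (1.47 ± 0.14). The falls were larger, in Tmem201 (-3.74 ± 0.32), Rara (-3.55 ± 0.20), Kif3c (-3.47 ± 0.26), Nfatc4 (-3.38 ± 0.13) and Kank3 (-3.19 ± 0.20). Some named local changes run against the change of their own gene. The M14 probes in Arl4c and Fgfbp1 fell where the genes rose, and the DZA probe in Rbmxl2 rose where the gene fell. A probe that does not follow its changed transcript gives such a value, so these need not be changes at the site. The rising M14 probes in Arl4c and Ccn1 went the same way as their genes. Some of these local changes share a short word on the RNA strand and may not be separate events. The rising probes in Adgra3, Plod1, Snx29 and Pcdh1 all hold GCCTGG, and the falling M14 probes in Vrtn, Spata13 and Mrps2 all hold CAGCATC. Both words were seen after the calls, and their cause was not tested.

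Probes that passed locally showed no detectable excess of the consensus DRACH, the sequence context of m6A. In M14 cells 40.5% of the probes that rose and 36.5% of those that fell held it, against 38.4% of all probes (Fisher's exact test, two-sided, p = 0.721 and 0.797). In DZA cells the shares were 30.4% and 24% (Fisher's exact p = 0.271 and 0.155). Local calls depended on the choice of arrays: with any 1 of the 9 arrays left out, calls numbered between 0 and 12 in M14 cells and between 4 and 51 in DZA cells.

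In local values the arrays did not gather by group. Across probes, M14_vs_SCR replicate 1 correlated at 0.842 and 0.770 with DZA_vs_SCR replicates 2 and 3 and at 0.805 with M14_vs_M14 replicate 1, but at 0.235 and 0.273 with its own replicates. The 3 DZA_vs_SCR arrays correlated at 0.644 to 0.773 with M14_vs_M14 replicate 1 and at 0.0707 to 0.401 with its replicates 2 and 3. Across genes the arrays did gather by group for M14_vs_SCR (0.882 to 0.965) and DZA_vs_SCR (0.881 to 0.944). DZA_vs_SCR replicates 2 and 3 thus belong to a set that holds 1 array of each other group. DZA_vs_SCR replicate 1 lies between the sets, at 0.570 with M14_vs_SCR replicate 1 and at 0.464 and 0.383 with its replicates 2 and 3. Local, single-probe and motif differences of DZA cells can therefore in part be differences between sets. Gene differences may be too, since the M14_vs_M14 arrays split in the same way across genes. How large a part was not tested. With the arrays numbered 1 left out of M14_vs_SCR and M14_vs_M14, 37421 local probes passed in DZA cells and 0 in M14 cells (limma, 25568 unadjusted). The 11 called falls with the word CGCCC did not follow the sets. Their median local value lay between -2.70 and -2.35 on the DZA_vs_SCR arrays. It was -0.25 on M14_vs_SCR replicate 1, which is not among the arrays compared to call them. The -0.06 on M14_vs_M14 replicate 1 was fixed in part by the choice of called falls.

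As a class, probes over GGACT, the most common form of DRACH, shifted slightly upward. On the M14_vs_SCR arrays the 10934 probes with a central GGACT exceeded 383036 GC-matched probes without DRACH by 0.018 ± 0.020 (SD, n = 3), and on the dye control arrays they lay at -0.014 ± 0.0089. The difference of 0.032 is 2.23% in the ratio (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows). M14_vs_SCR replicate 1 gave 0.041, and without it the difference was 0.021. On the DZA_vs_SCR arrays the same probes exceeded the others by 0.0082 ± 0.011, a difference of 0.022 or 1.54% (exact permutation p = 0.1). Part of it can come from the sets, since M14_vs_M14 replicate 1 lay at -0.0036 and the DZA_vs_SCR arrays at -0.0024, 0.0077 and 0.019. By replicate number M14_vs_SCR exceeded M14_vs_M14 by 0.044, 0.029 and 0.022. DZA and M14 did not differ in this beyond their spread (-0.0098, exact permutation p = 0.6).

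Ranked by the same local change among all 1024 pentamers, GGACT was number 12 in M14 cells and number 47 in DZA cells. In M14 cells 16 of the 20 highest pentamers held a purine followed by AC, as 96 of the 1024 do, with GAACT first at 0.038 and TGGAC next at 0.037. In DZA cells 3 of the 20 did. TGTGT, which holds no such site, was highest in DZA cells (0.038) and lowest in M14 cells (-0.040).

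**Figure D5:**
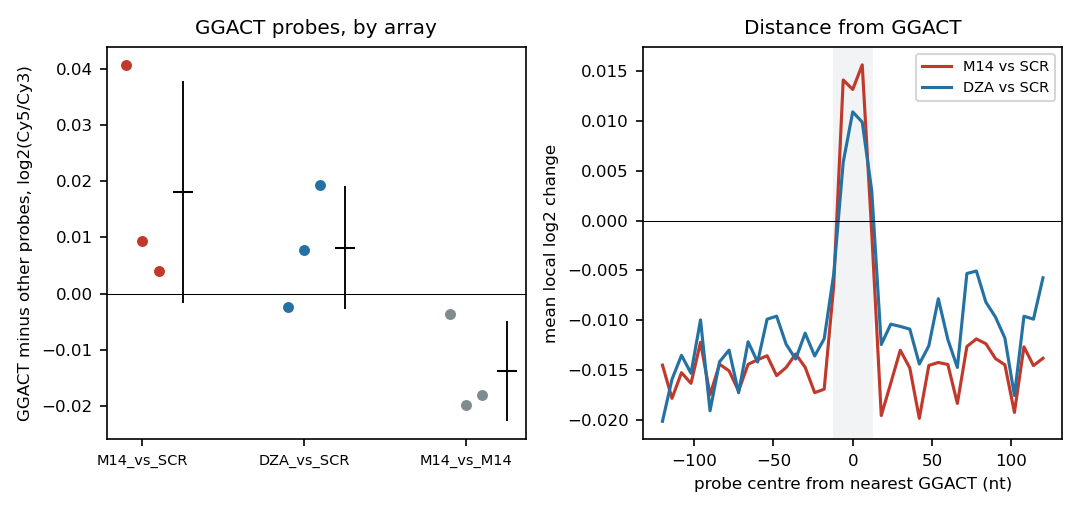
Left, mean log2(Cy5/Cy3) of GGACT probes minus GC-matched probes without DRACH on each of the 9 arrays (points), with group mean and SD. Right, mean local log2 change by distance of the probe centre from the nearest GGACT, in nt, for M14 (red) and DZA cells (blue); the shaded probes, within 12 nt, cover the site, and the M14 curve reaches 0.016 there.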

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

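All tests on the GGACT distance profile, on the arrays without replicate number 1, on shared probe words and on background correction were set before their results were seen. The tests on the spread of the naive genes, on the orders of the GGACT bases, and on GC content and Cy3 at the CGCCC probes were chosen after the pattern was seen.

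A difference between groups marked 10 of the named genes and regions, which were called in opposite directions in M14 and DZA cells and differed in the direct test. S100a7l2 (-1.27 ± 0.10 in M14, 0.45 ± 0.10 in DZA, difference 1.72), Fgf12 (difference 1.54) and the regions at chromosome 3 6297908 (1.49), chromosome 2 22002292 (1.48) and chromosome 4 75354636 (1.33) share probe words with one another. Gm35197 went from -0.55 ± 0.09 to 1.17 ± 0.09 (1.72), and the region at chromosome 9 50085991 from -0.65 ± 0.09 to 0.94 ± 0.09 (1.59). Rian differed by -1.48, the region over Stk16 and Tuba4a by -1.04 and Mdm2 by 1.03 (-0.16 ± 0.05 in M14, where it reversed to 0.0024 under median centring, and 0.87 ± 0.05 in DZA). Of all 6038 genes and regions, 181 did so.

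A signal outside the main measurement came from the 50 tiled regions named neg in the files. In M14 cells 10 of them were called (6 higher, 4 lower), 20% against 25.4% of the m6a regions. In DZA cells 20 were called (16 higher, 4 lower), 40% against 41.3%. Their per-array median, relative to the m6a regions, differed from the dye controls by -0.0035 in M14 (exact permutation p = 1) and by 0.022 in DZA (exact permutation p = 0.1, the smallest possible).

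Splits of the 6 arrays of a comparison into 3 and 3 number 10, too few for a share under 0.05. The real split was the 1 split of 10 with as many calls for 6097 probes, 1731 genes and 137 local probes in M14, and for 17883 probes, 2564 genes and 81 local probes in DZA, where the highest other split gave 0 each. It was also the 1 split of 10 for the 2730 genes that differ between DZA and M14, where the highest other split, DZA_vs_SCR replicate 1 with M14_vs_SCR replicates 2 and 3, gave 186. For gene lists the real split gave 3 in M14 and 3 of 10 splits gave as many (highest other 3); in DZA, and between DZA and M14, it gave 0, and 10 of 10 splits gave that many or more (highest other 1 and 3). In M14, where numbers may pair the arrays, the 3 other splits that part all 3 pairs called 0 genes and between 1 and 3 lists. The 6 that part 1 pair called 0 genes and between 0 and 3 lists.

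The naive pluripotency genes fell in M14 cells by a median of 0.25 on the log2 scale. A smaller share of stem cells among the cells, which grew on feeder fibroblasts, would lower all 14 alike if the other cells held none of these transcripts. That was not measured. The SD of the 14 changes was 4.06 times their median SE, with Tet2 at -0.61 and Sox2 at -0.05. Of the feeder markers, Ccn1 (1.51 ± 0.18) and Twist1 (0.40 ± 0.09) rose by unlike amounts while Col5a1 (0.16 ± 0.08) did not pass. The unlike falls argue only against an equal dilution of all 14, and a smaller share of stem cells stays open. The brighter Cy5 of the arrays numbered 1 would end the fall without them, but the median was then -0.23, and probes that read related transcripts would end it over unshared probes, where it was -0.24. A change in the state of the cells may remain, as a hypothesis: the list test did not pass with an estimated correlation, and 3 of 10 splits gave as many lists.

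GGACT probes shifted upward in M14 cells. If a methyl group weakens pairing with the probe, loss of Mettl14 would raise probes over the site, and probes that cover GGACT did exceed GC-matched probes 25 to 100 nt away by 0.025 more than on the dye controls (exact permutation p = 0.1, 28979 covering probes). Base composition of the probes would give other orders of the same 5 bases as large a shift, but GGACT ranked 2 of 60 orders of G, G, A, C and T, after TGGAC, with a median of 0.0031 for the others. What stays open is an effect of the word itself on the dyes, since most covering probes hold it. Covering was set by the adenosine, within 12 nt of the probe centre, and 24903 probes hold the whole word, against 28979 that cover the adenosine. A loss of m6A may account for the shift, and the place of the site in the probe does not decide it, since probes with the site at their centre minus those with it at their edge gave -0.0011, -0.012 and -0.013 on the M14_vs_SCR arrays against 0.00012, -0.011 and -0.0054 on the dye controls.

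The local falls of DZA cells gathered on probes with CGCCC on the RNA strand: 11 of the 25 called falls held it (44%), against 2.28% of all probes. GC-matched probes without the word, or probes with its reverse complement, fell beyond 1.5 at most 0.056 times as often (0.0107% against 0.191%). The word was picked from these same falls, which are counted in its rate. The comparison therefore cannot decide whether base composition accounts for them. Background correction of dim spots would shrink without it, but the median change of the 11 was -3.09 with none and -2.58 with it. Another RNA in the SCR sample would raise Cy3 over that of the M14_vs_SCR arrays, yet the difference was 0.036 while the Cy5 difference was -1.96. An RNA that DZA cells lack and that M14 and SCR cells hold may be the cause, which no test here addressed.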

How the results depend on the processing

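The block over the M14_vs_SCR and M14_vs_M14 arrays only, the arrays numbered 2 and 3, the channel balance covariate and the unshared probes were alternatives chosen after the data were seen. Of the values of named genes under all alternatives, 4710 kept their side of the threshold, 379 no longer passed, 94 newly passed and 16 reversed. A change of direction was counted as a reversal only where the value passed in the main fit or in the alternative. Values that passed in neither fit are among the 4710 whatever their direction. Median centring without loess gave 171 of the 379 and 15 of the 16. Where no cause is given, the cause was not tested.

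With median centring, limma called 0 genes in M14 (721 at an unadjusted p below 0.05), 0 in DZA (731) and 0 between DZA and M14 (271). It called 562 probes and 0 local probes (14447 unadjusted) in M14, and 0 probes (50513) and 0 local probes (33829) in DZA. The reversed values were Socs3 0.019, Spry2 0.025 and Mdm2 0.0024 in M14; Socs3 0.20, Aurkb 0.33, Klf10 0.082, Cebpb 0.062, Mat2a 0.17, Gdf3 0.059, Klf2 0.31, Foxd3 0.099 and Neat1 0.43 in DZA; and Aurkb 0.15, Rbm15b 0.021 and Mtap 0.056 between DZA and M14. The median of all genes in DZA was 0.13 with this centring and 0.11 with Agilent's processed signals, against 0.0090 with loess. With those signals 1341 of 1836 genes rose in DZA, and 1343 of 2079 were higher in DZA than in M14. Without the dye control Hnrnpd reversed in M14 (-0.056), and 1328 of 3046 genes rose.

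Probes called in M14 numbered 10971 without background correction, 16936 with Agilent's signals, 63257 without the dye control, 4034 with the replicate block, 41872 with that block over the M14_vs_SCR and M14_vs_M14 arrays only and 20408 with the channel balance covariate. In DZA they numbered 3076 with Agilent's signals, 1365 with the series matrix, 196164 without the dye control and 98989 with arrays numbered 2 and 3. Arrays numbered 2 and 3 gave 914 genes in M14, the replicate block 1276 and the block over the paired arrays only 1566. With the block 2274 genes were called in DZA and 2435 between DZA and M14.

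Local probes called in M14 numbered 0 with the series matrix (limma, 31002 unadjusted), 978 without the filter, 33 with spots well above background on all 9 arrays, 13770 without the dye control, 0 with the replicate block (24054 unadjusted), 208 with the gene median taken out, 4060 with the block over the paired arrays, 0 with arrays numbered 2 and 3 (25568 unadjusted) and 1131 with the covariate. In DZA they numbered 53 without background correction, 16 with Agilent's signals, 15 with the series matrix, 2369 without the filter, 37 on all 9 arrays, 110581 without the dye control, 6 with the block, 122 with the gene median, 37421 with arrays numbered 2 and 3 and 632 with the covariate.

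With 1 array left out, counts ran from 1658 to 5045 probes, 744 to 2047 genes and 0 to 12 local probes in M14; from 1486 to 34087 probes, 1822 to 3245 genes and 4 to 51 local probes in DZA; and from 2176 to 2886 genes between DZA and M14. Genes in M14 fell to 850, 755 and 744 without M14_vs_M14 replicates 1, 2 and 3. Local counts changed over 1.5 times without any of the 9 arrays. The GGACT difference stayed above 0 throughout, between 0.018 and 0.074 in M14 and between 0.0082 and 0.053 in DZA, and between 0.021 and 0.039 and between 0.016 and 0.027 with 1 array left out.

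Lists in M14 numbered 0 with an estimated correlation (camera), 6 with fry, 1 with the block over the paired arrays and 3 without any 1 array. In DZA fry called 8, and camera at the preset correlation called 0, also with any 1 array left out. Those 8 were the integrated stress response, p53, lineage differentiation, interferon, Polycomb, m6A writer and eraser, m6A reader and naive pluripotency lists. Between DZA and M14 the number was 1 without background correction, 3 with Agilent's signals, 3 with median centring, 3 with the series matrix, 1 without the filter, 2 on all 9 arrays, 3 with the gene mean, 7 with fry, 2 with the covariate, 1 over unshared probes and 0 to 1 with 1 array left out. The immediate early and primed lists in M14 both had an adjusted p of 0.0557 with the block over the paired arrays. The naive list's median in M14 ran from -0.41 to -0.10, with adjusted p from 5.85e-08 to 0.0732, above 0.05 only with the estimated correlation.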

Other observations

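All values in this part were chosen after the data were seen. Units whose kept probes share words of 14 nt formed 17 families with 364 members. The family of S100a7l2, Fgf12 and Gng12 holds 15 units, of which 12 fell and 2 rose in M14 cells, with a median change of -0.95, and 10 rose in DZA cells, with a median of 0.25. Its per-array mean was -0.88 ± 0.01 (SD, n = 3) on M14_vs_SCR, 0.16 ± 0.10 on DZA_vs_SCR and -0.10 ± 0.05 on M14_vs_M14. With limma's camera at the preset correlation its adjusted p over 17 families was 2.25e-09 in M14 cells, and with an estimated correlation it did not pass (adjusted p 0.239, unadjusted 0.0281). A family of 7 unnamed regions, among them those at chromosome 18 9595678 and chromosome 4 41878794, went the other way. All 7 rose in M14 cells (median 0.67) and 3 fell in DZA cells (median -0.23); with an estimated correlation it did not pass in M14 (adjusted p 0.239, unadjusted 0.0561). These members are not independent measurements, since their probes share sequence.

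Of the 32 fibroblast feeder markers listed before the data were examined, 4 were measured, of which 3 are given here. Ccn1 (1.51 ± 0.18) and Twist1 (0.40 ± 0.09) rose in M14 cells, and Col5a1 (0.16 ± 0.08) did not pass. Ccn1 (1.33 ± 0.18) and Col5a1 (0.26 ± 0.08) rose in DZA cells, and Twist1 (0.13 ± 0.09) did not pass.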
